A study of Homo sapiens with 5 samples.

How the data were processed

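Guide RNA abundance was measured by sequencing in 5 libraries from HepG2, an established human liver cancer cell line. The cells had been infected with a lentiviral knockout library in lentiCRISPRv2, a vector that carries Cas9 together with 1 guide. The library targets chromatin and RNA regulators and includes 131 guides with no target in the genome (non-targeting guides). The labels give 1 untreated library, 2 libraries after 15 days in DMSO, the solvent, and 2 libraries after 15 days in 5 µM sorafenib, a multikinase inhibitor used against liver cancer. When the untreated cells were collected is not given in the sources used here. Nothing in the labels says that the 2 libraries of a group came from separate cultures, so p-values measure the spread between libraries, which may be technical.

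Per the labels' protocols, the guide region was amplified by PCR from genomic DNA and sequenced on an Illumina instrument. Per the submitters' processing notes, MAGeCK was used. Its version, and any genome build, are not given in the sources used here. The deposited table holds, for each guide and library, a signal that is a read count divided by a size factor of the library, called normalized count below. Within a library, 100% of the values were whole multiples of the value of 1 read, within a tolerance of 1e-06, so read counts could be recovered. An automatic test of this property passed for DMSO library 1, and the other libraries hold too few low values for it. Reads were not tagged with molecular identifiers in the sources used here, so intervals from read counts cover counting error only.

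The table held 5582 guides, 66 fewer than the 5648 the labels state. Of these, 5451 targeted 910 genes, 905 of them with 6 guides. Gene names are those of the table, which include older symbols. In RefSeq names of assembly GRCh38.p14, 866 of the 910 names are current symbols, 41 match 1 newer symbol and 3 have no single match. Genes of multi-copy families can share cutting sites and are uncertain.

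Values were analysed as log2(normalized count + 1), and a fold change is on that scale, which understates changes of low guides. Guides with a mean under 10 over the libraries were left out (56 guides). This left 5526 guides and, with at least 3 guides required, 909 genes. For each gene and library the mean over its guides was taken. These means were compared between groups with limma 3.58.1 in R 4.3.3, with all 5 libraries in 1 fit, 2 residual degrees of freedom and Benjamini-Hochberg adjustment over the genes (threshold 0.05). Single guides were tested the same way with a variance trend. The comparisons with the untreated group assume that its 1 library varies like the others. The 3 comparisons share libraries, so they are not independent of each other.

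Further gene-level settings were planned as alternatives, among them the median over guides, a variance trend, and robust rank aggregation, the kind of test MAGeCK uses (alpha 0.25, guides ranked by limma's statistic, 100000 random guide sets, adjustment per direction). The rank test asks whether a gene's guides lie together at 1 end of the ranking. It treats guides, not libraries, as the units. Recovered reads were tested per guide with edgeR 4.0.16 (quasi-likelihood test) and DESeq2 1.42.0. Other alternatives were scaling on the non-targeting guides or to equal totals, a pseudocount of 10, a mean of at least 100 or no filter, each replicate left out, the replicate number as a block, and only the groups compared. Weights per library and the rank test under these alternatives were added after the data were seen. So was the Mediator list under them, except for scaling on the non-targeting guides, which was planned.

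Gene lists were tested with camera (preset correlation 0.01, and again with the correlation estimated) and with fry, which tests a list against no change and not against the other genes, both in limma, with Benjamini-Hochberg adjustment over the lists of a comparison. With the correlation estimated, camera tests on the 2 residual degrees of freedom, which leaves it little power. Of the lists fixed before the data were examined, 26 had at least 5 measured genes. A further 13 such lists were made from the gene names of the library, before any change was computed, and adjusted separately. Lists of ferroptosis genes, of MAPK signalling genes and of Hippo and growth control genes had 0 measured members and were not tested. A list of iron regulators had 2 members and was not tested either.

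The genes named were chosen by a rule fixed before the data were examined. It takes up to 10 genes per direction past limma's test, filled to 5 by the smallest unadjusted p where fewer pass, always CARM1, and up to 3 members of each list. The genes past the rank test and further Mediator genes outside this rule were named after their values were seen. CARM1 was also set against 100000 draws of as many non-targeting guides. Non-targeting guides were grouped into 21 pseudo-genes of 6 guides and passed through the same tests.

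The tests were run first on simulated counts for the sorafenib and DMSO comparison with 909 genes, drawn from negative binomial distributions. With limma on gene means, 70% of genes lowered by a log2 of 1 and 76% of those raised by 1 were found, and 92% and 98% at a log2 of 2. Of 709 unchanged genes, 11 were called. The rank test found 68%, 72%, 96% and 98% of the same genes and called 0 unchanged ones. The simulated noise had no component shared by the libraries of a group, and it was equally wide in both groups. In the data the DMSO pair was wider than the sorafenib pair (SD of the log2 difference 1.60 and 0.69). The shares found need not hold for this screen. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the other steps.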

Results

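The screen measured how the abundance of 5582 guides differed between HepG2 cells that were left untreated (1 library), kept in DMSO for 15 days (2 libraries) or kept in 5 µM sorafenib for 15 days (2 libraries). A guide that becomes scarcer can mark a gene whose loss slows growth or survival in that condition, relative to the other cells. A guide that becomes more abundant can mark the opposite. Non-targeting guides changed too, as given below, so a changed guide need not mark an effect of its gene. The libraries held 24481840 reads (untreated), 22153681 and 25601619 (DMSO 1 and 2) and 24055644 and 24153976 (sorafenib 1 and 2), with medians of 2410.5 to 3067.5 reads per guide.

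Guides were less evenly spread in the DMSO and sorafenib libraries than in the untreated one, a difference that was not tested. The Gini index, which is 0 when all guides have equal reads, was 0.502 in the untreated library, 0.567 in both DMSO libraries, and 0.557 and 0.553 in the sorafenib libraries. Both DMSO values lay above both sorafenib values, but with 2 against 2 libraries no two-sided exact permutation test can give a p under 0.333. DMSO 1 stood apart from the rest: 232 guides had 0 reads in it, against 77 in the untreated library, 90 in DMSO 2, and 108 and 103 in the sorafenib libraries. A count of 0 allows up to 3 reads, a normalized count of 3.37 in DMSO 1. None of the 131 non-targeting guides was at 0 in any of the 5 libraries. The SD of the log2 difference between the libraries of a pair was 1.60 over guides for DMSO and 0.69 for sorafenib. Neither pair agreed within sampling noise (chi-square per degree of freedom 168.6 and 42.9), a spread that repeat amplifications of 1 DNA sample could also give.

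**Figure D1:**
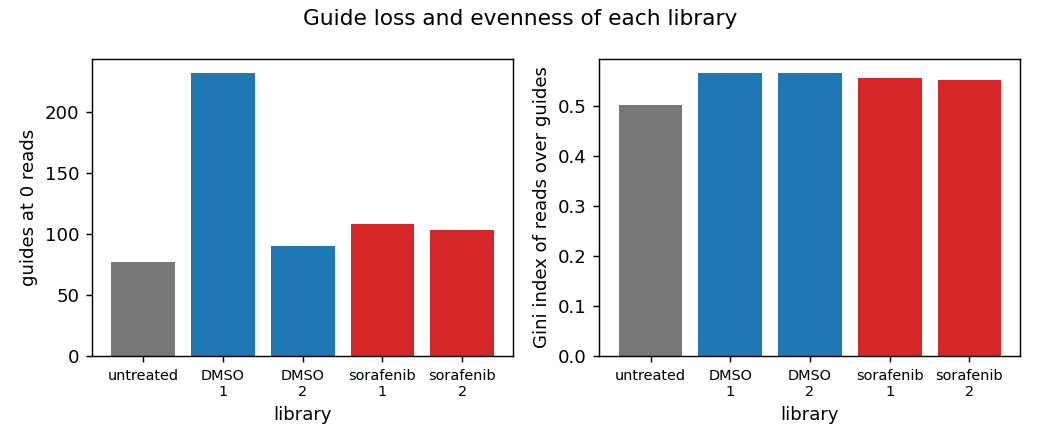
Number of guides at 0 reads (left) and Gini index of reads over guides (right) for each of the 5 libraries, coloured by group. DMSO 1 has 232 guides at 0, while the other libraries have 77 to 108.

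CARM1, an arginine methyltransferase that acts as a transcriptional coactivator, is the gene the study's title names. All 6 of its guides were scarcer in sorafenib than in DMSO. The mean over its guides was 12.61 and 12.95 in DMSO 1 and 2 on the log2 scale and 11.57 in both sorafenib libraries, against 12.52 in the untreated library. This is a log2 change of -1.21 ± 0.16 (SE), or 2.31-fold lower in sorafenib. The most depleted guide had normalized counts of 3101 and 3194 in DMSO and 456 and 572 in sorafenib (log2 -2.62). The least depleted had a log2 change of -0.25. Of the 6 guides, 3 passed limma's guide test (log2 -1.12, -1.03 and -2.62).

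CARM1 as a gene did not pass limma's test of gene means (unadjusted p = 0.00294, adjusted p = 0.107). Limma's adjusted p was 0.0202 with a variance trend, 0.0542 with the median over guides and 0.309 with the replicate number as a block. It was 0.0403 without DMSO replicate 1, 0.0089 without DMSO replicate 2, 0.79 without sorafenib replicate 1 and 0.746 without sorafenib replicate 2. In the rank test its adjusted p was 0.439, and it passed in 1 of 10 other settings. Of 100000 random draws of as many non-targeting guides, none had a mean as low (-0.96 to 1.54), and the share as far from the non-targeting mean on either side was 4e-05, counting CARM1 itself. Such draws treat guides, not libraries, as the units. They are also a narrow reference: their SD was 0.28, against a median SD of 0.53 for gene means when targeting guides were dealt to genes at random. The study chose CARM1 on these samples, so its values are not independent evidence.

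**Figure D2:**
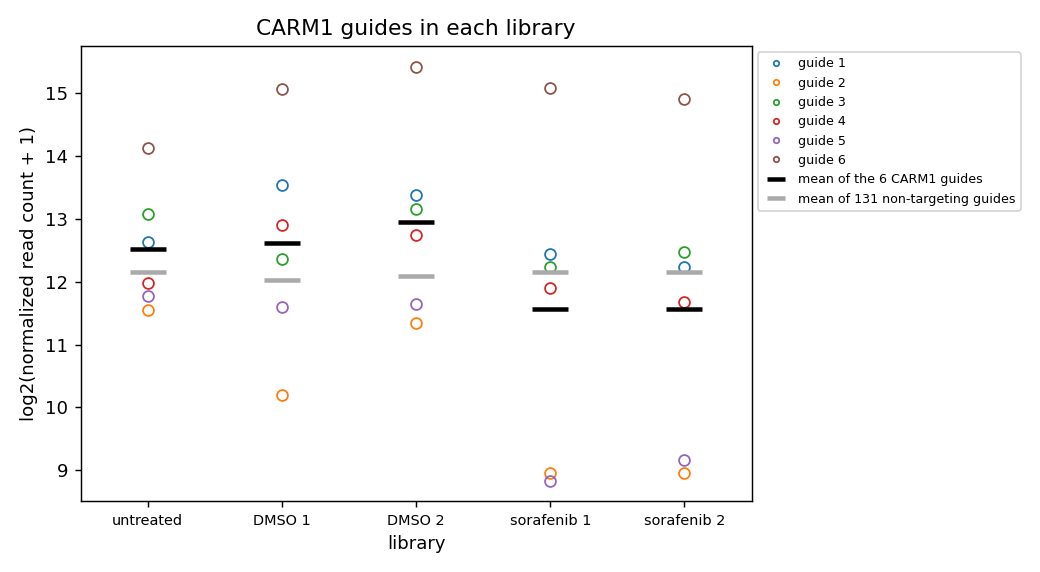
Abundance of the 6 CARM1 guides, as log2(normalized read count + 1), in each of the 5 libraries, with the mean of the 6 guides (black bars) and of 131 non-targeting guides (grey bars). The black bar is at 12.61 and 12.95 in DMSO and at 11.57 in both sorafenib libraries, while the grey bar stays between 12.03 and 12.15.

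The comparison of sorafenib with DMSO asks which knockouts change how cells fare under the drug. Among the genes with the smallest p in each direction, guides against TRIM33, a ubiquitin ligase of TGF-beta signalling, were 2.85-fold lower in sorafenib (log2 -1.51 ± 0.13, 6 of 6 guides lower). Guides against ATF7IP, a partner of the histone methyltransferase SETDB1, were 2.61-fold lower (log2 -1.38 ± 0.11, 5 of 6 guides). ING2, a subunit of SIN3 histone deacetylase complexes, was at -1.05 ± 0.10 (5 of 6) and the remodeler CHD1 at -0.99 ± 0.10 (4 of 6). TARDBP, an RNA-binding protein, was at -1.31 ± 0.15, but 2 of its 5 tested guides were lower and the sign turned to 0.46 with the median over guides. The genes with higher values and the smallest p were SRRT, which links the RNA cap-binding complex to RNA processing (1.57 ± 0.14, 4 of 6 guides higher), the bromodomain reader ZMYND8 (1.28 ± 0.13, 6 of 6), the nucleosome-binding HMGN2 (1.19 ± 0.11, 4 of 6), PPFIA1 (1.18 ± 0.11, 5 of 6) and the Mediator subunit MED15 (1.12 ± 0.10, 5 of 6). A few guides carried some of these means: the median log2 ratio of the guides was 0.58 for SRRT, 0.63 for ZMYND8 and -0.46 for ING2, and for HMGN2 the only guide past limma's guide test was lower.

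None of these passed limma's test of gene means. It called 0 of 909 genes, and the smallest adjusted p was 0.0894. The unadjusted p was under 0.05 for 204 genes (22.4%) and for 2 of 21 non-targeting pseudo-genes (9.52%). In the rank test 59 genes were lower and 53 higher at that threshold, and 2 of 21 pseudo-genes reached it in either direction. Other ways of testing gave other counts: 82 genes with the median over guides, 36 with a variance trend and 7 with the rank test. With a single DMSO library the spread comes from the closely matched sorafenib pair alone, and limma then called 48 genes without DMSO replicate 1 and 360 without DMSO replicate 2.

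The 7 genes past the rank test were 2 with scarcer guides in sorafenib, ATF7IP and SPEN, and 5 with more abundant ones, BRD1, MED15, IREB2, USP22 and CHD7. They were singled out after their values were seen. ATF7IP and SPEN, a transcriptional corepressor (log2 -0.81 ± 0.11, 6 of 6 guides), had rank test p-values of 1e-05, the smallest that 100000 random sets can give, and adjusted p-values of 0.00454. BRD1, a scaffold of histone acetyltransferase complexes, was 2.19-fold higher (log2 1.13 ± 0.12, 6 of 6 guides, rank test adjusted p = 0.00909). MED15 and IREB2, the iron regulatory protein that controls mRNAs of iron uptake and storage (log2 1.24 ± 0.14, 5 of 6 guides), had rank test adjusted p-values of 0.0205. So did USP22, the deubiquitinase of the SAGA coactivator (log2 0.81 ± 0.10). The remodeler CHD7 was at 0.83 ± 0.10 (rank test adjusted p = 0.0345), with 6 of 6 guides higher for both USP22 and CHD7. None of the 21 non-targeting pseudo-genes passed the rank test. With 7 of 909 genes called, 21 sets are too few to show how often it calls guides with no target. Without DMSO replicate 2 only ATF7IP passed (adjusted p = 0.0364). Without DMSO replicate 1 ATF7IP, SPEN and BRD1 passed, joined by CARM1 and TRIM33, and without sorafenib replicate 1 ATF7IP, SPEN, BRD1 and TRIM33 passed.

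**Figure D3:**
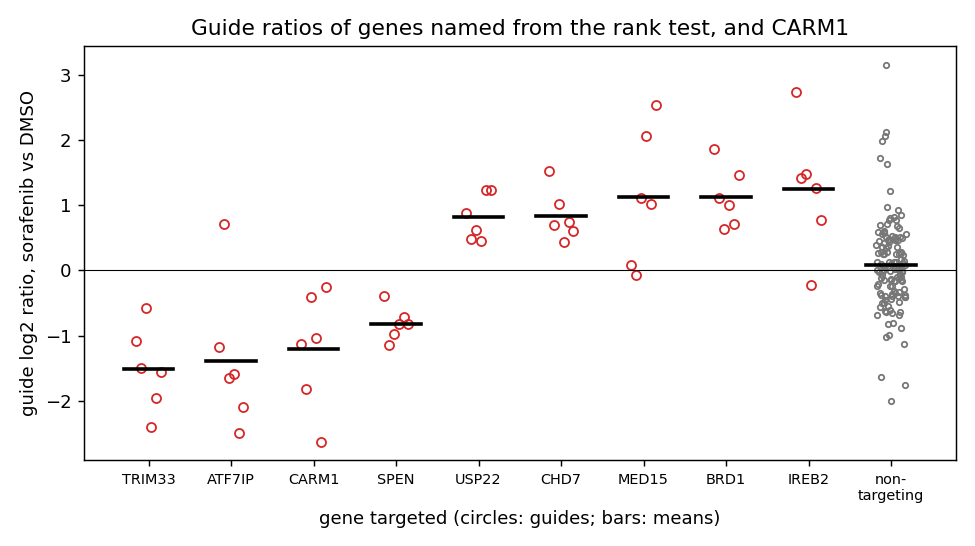
Log2 ratio of sorafenib over DMSO for each guide (circles) of the 7 genes past the rank test, TRIM33 and CARM1, and for 131 non-targeting guides, with the mean of each set as a bar. Every guide of SPEN, TRIM33 and CARM1 lies below 0 and every guide of BRD1, USP22 and CHD7 above 0, while non-targeting guides range from -1.99 to 3.15.

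Guides against Mediator, the complex that connects transcription factors with RNA polymerase II, were higher as a group in sorafenib against DMSO by camera with its preset correlation, but not with the correlation estimated. Of 30 measured Mediator genes, 24 had a log2 change above 0, with a median of 0.57 against 0.09 for all genes (camera, adjusted p = 0.00137, and adjusted p = 0.961 with an estimated correlation). The largest values were those of MED26 (2.14 ± 0.62), MED10 (2.07 ± 0.56), MED30 (1.78 ± 0.33) and MED23 (1.72 ± 0.32), named after they were seen. MED13L of the kinase module stood at 1.56 ± 0.16 and MED16 of the tail module at 0.98 ± 0.13. In DMSO against untreated, MED26, MED10, MED30 and MED23 were at -2.17, -0.83, -2.75 and -1.17, and MED13L and MED16 at 0.20 and -0.38. Both comparisons use the DMSO libraries, so low values there raise the first and lower the second. In sorafenib against DMSO, at an unadjusted p under 0.05, 14 of the genes were higher and 1, MED6 (-0.42), was lower. Adjusted over the list alone, 8 passed, all of them higher, and 0 passed over all genes. The list fixed beforehand for Mediator and transcription elongation had 7 measured genes, all above 0, with a median of 0.87 (adjusted p = 0.00612), among them MED1 (0.87 ± 0.11) and the elongation factor SUPT6H (1.01 ± 0.16, 2 of 6 guides higher). Its call was lost too with an estimated correlation (adjusted p = 0.906), in which no list passed. That estimate was -0.11, below the preset 0.01, so correlation between its genes does not account for the loss. This variant of camera tests on 2 residual degrees of freedom, so lost calls do not show that genes vary together. Without DMSO replicate 2 the adjusted p-values of the Mediator list and of this list were 0.0634 and 0.204. With fry, which tests a list against no change and not against the other genes, they were 0.0765 and 0.0283.

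**Figure D4:**
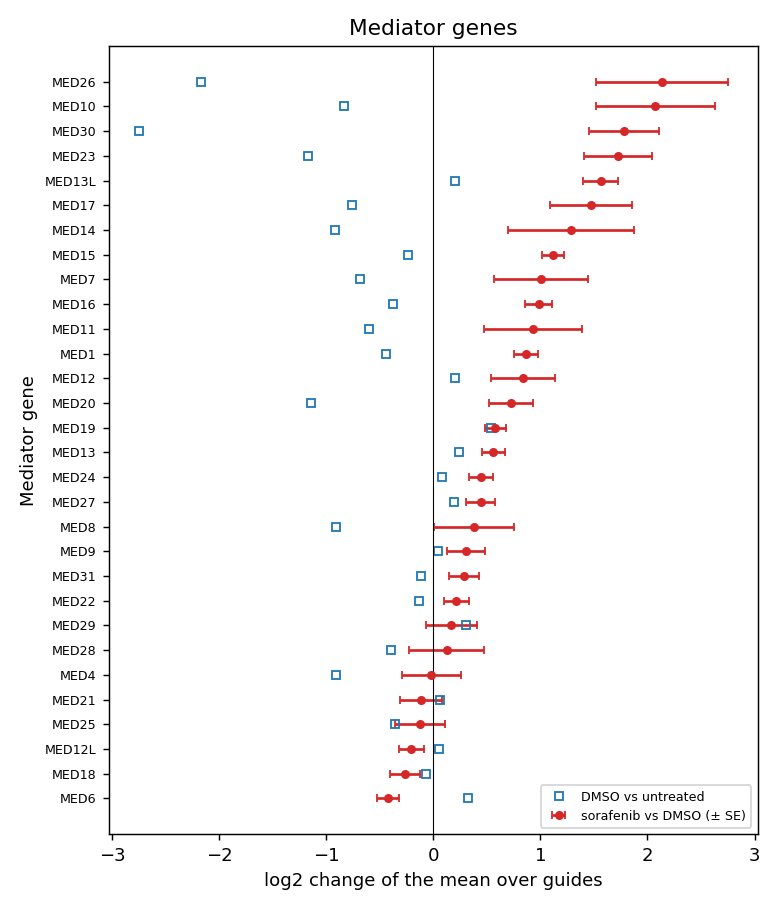
Log2 change of the mean over guides for the 30 Mediator genes in sorafenib against DMSO (filled circles, bars show the SE) and in DMSO against untreated (open squares). In sorafenib against DMSO 24 of the 30 genes lie above 0; the 2 sets of points share the DMSO libraries, so noise in those libraries moves them apart.

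No other list passed camera in this comparison (adjusted p-values from 0.414 to 0.983 for the lists fixed beforehand and from 0.914 to 0.924 for those made from the library's names). Among 9 arginine methyltransferases, the family of CARM1, the median was -0.23 and 6 were below 0 (adjusted p = 0.424). Adjusted over the list alone 3 passed, PRMT3 (1.32 ± 0.14, 6 of 6 guides higher), PRMT1 (0.55 ± 0.10) and CARM1, which the study picked from these libraries. PRMT3 was at -1.42 in DMSO against untreated, so low DMSO values could give both of its changes. Of 16 bromodomain and TRIM readers 5 passed over the list alone, 4 higher and 1 lower, and the list's median was 0.07 (adjusted p = 0.875). For 21 histone acetyltransferases the median was 0.33 (adjusted p = 0.414), among them GTF3C4 at 2.16 ± 0.31. Its guides were rare, with means of 4.79 in DMSO and 6.95 in sorafenib on the log2 scale. Of its 6 guides 4 were higher, 1 of them past limma's guide test. The 5 measured SAGA and ATAC genes had a median of 0.61, 4 of them above 0 (adjusted p = 0.414). Of 16 genes of corepressor complexes 9 were above 0, with a median of 0.07 (adjusted p = 0.875), among them KDM1A at 0.58, while SIN3B was at -0.64 ± 0.11, with 6 of 6 guides lower.

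Single guides changed in number: 447 fell and 365 rose in sorafenib against DMSO, 812 of 5526 tested (limma with a variance trend). Non-targeting guides did so at a like rate, 21 of 131 (16.0%), against 791 of 5395 targeting guides (14.7%). The SD of the guide log2 ratio was 0.70 over non-targeting and 1.30 over targeting guides. With edgeR 1004 guides were called and with DESeq2 2319, of which 25 and 54 were non-targeting. Leaving out either sorafenib library left 0 calls, while leaving out DMSO 1 or DMSO 2 gave 1266 and 2192.

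DMSO was compared with the untreated cells to see which guides differ without the drug, though it is not known how far this reflects time in culture. The lowest value among genes chosen by their p was that of MED30, whose guides were 6.73-fold lower in DMSO (log2 -2.75 ± 0.40). PRMT3 (-1.42 ± 0.17), the small nuclear ribonucleoprotein LSM10 (-1.37 ± 0.15), SUZ12 of the Polycomb complex PRC2 (-1.35 ± 0.18) and SRRT (-1.19 ± 0.17) were also lower. With the median over guides, PRMT3 and LSM10 turned to 0.01 and 0.06, and the median log2 ratio of the guides was -0.02 for SRRT, -0.47 for SUZ12 and -1.35 for MED30. The cohesin subunit RAD21 was at -3.08 ± 0.96, and the cullins CUL2 and CUL3, scaffolds of ubiquitin ligases, at -2.45 ± 0.43 and -1.87 ± 0.42. The highest values chosen by p were those of the condensin subunit SMC4 (1.82 ± 0.38), the RNA-binding RBM3 (1.32 ± 0.15), ZFP36 (1.08 ± 0.22), TP63 (0.76 ± 0.13) and WDSUB1 (0.70 ± 0.13), with guide medians of 0.70 for SMC4, 0.28 for RBM3, 0.25 for ZFP36 and 0.09 for WDSUB1. CARM1 was at 0.26 ± 0.20, with 3 of 6 guides higher (limma, adjusted p = 0.587). MED30, PRMT3, SUZ12, SRRT and ZMYND8, the last at -1.03 ± 0.16 here, were higher in sorafenib against DMSO. Both comparisons use the DMSO libraries, so low DMSO values could give both changes.

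None of 909 genes passed limma's test in this comparison (smallest adjusted p = 0.369) or the rank test. At an unadjusted p under 0.05 there were 102 in limma (11.2%), against 1 of 21 non-targeting pseudo-genes (4.76%). In the rank test 45 were lower and 48 higher at that threshold, and 6 of 21 pseudo-genes reached it in either direction. Without DMSO replicate 2, limma called 276 genes, 239 of them lower. Of 39 genes listed as cell-essential, 25 were below 0, with a median of -0.41, and 11 were lower at an unadjusted p under 0.05, among them RBBP5 (-1.28 ± 0.19) and the acetyltransferase KAT5 (-1.09 ± 0.18), but the list did not pass (camera, adjusted p = 0.364). Of 41 core spliceosome genes 36 were below 0, with a median of -0.51 (adjusted p = 0.241). The median of 21 histone acetyltransferases was -0.68 (adjusted p = 0.344) and that of Mediator -0.30 (adjusted p = 0.62). All genes had a median of -0.12, and scaling to equal totals shifted it by -0.20 (by -0.16 in sorafenib against untreated). Among guides 3 rose and 0 fell in limma's guide test, while with no filter 4 rose and 17 fell. With edgeR, which called 61, 57 rose and 4 fell. With DESeq2, which called 1280, 855 rose and 425 fell. Without DMSO replicate 1 and 2 limma called 167 and 1245 guides, and 0 without either sorafenib library.

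Sorafenib was also compared with the untreated cells, a comparison that uses no DMSO library except for the shared estimate of the spread. TRIM33 and ATF7IP passed the rank test as lower in sorafenib, both with an adjusted p of 0.00454. TRIM33 guides were 3.34-fold lower (log2 -1.74 ± 0.16, 6 of 6 guides) and ATF7IP guides 1.89-fold lower (log2 -0.92 ± 0.13, 5 of 6 guides). Both passed in each of the 9 other settings of the rank test. Other genes with lower values and the smallest p were TARDBP (-1.95 ± 0.18, 3 of 5 tested guides lower), ING1 (-1.68 ± 0.21, guide median -0.73), a subunit of SIN3 complexes like ING2, and CHD1 (-0.89 ± 0.12). CARM1 was at -0.95 ± 0.20, with 5 of 6 guides lower (limma, adjusted p = 0.21), and at -0.30 with the median over guides. Its adjusted p was 0.036 without DMSO replicate 1 or 2, 0.942 without sorafenib replicate 1 and 0.969 without sorafenib replicate 2. The genes with higher values and the smallest p here were MED13L (1.76 ± 0.20), PPFIA1 (1.34 ± 0.13), TP63 (1.12 ± 0.13), MED19 (1.12 ± 0.12) and RBM3 (1.11 ± 0.15), and RBM3 turned to -0.04 with the median over guides.

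Limma called 0 of 909 genes here (smallest adjusted p = 0.21), with 142 at an unadjusted p under 0.05. It called 40 with the median over guides, 13 with a variance trend, and 107 without either DMSO library, where the spread comes from the sorafenib pair alone. Mediator genes were higher as a group by camera with its preset correlation only (median 0.34, 19 of 30 above 0, camera adjusted p = 0.0263, and adjusted p = 0.914 with an estimated correlation), as did the 7 genes of the Mediator and elongation list (median 0.53, adjusted p = 0.0425, and adjusted p = 0.985 with an estimated correlation). Without sorafenib replicate 2 these adjusted p-values were 0.158 and 0.0754. No list besides these passed. Among 11 genes of the COMPASS and MLL complexes, which methylate histone H3, 1 was above 0, ASH2L (1.46 ± 0.33). Their median was -0.49 (camera, adjusted p = 0.184). In limma's guide test 315 guides rose and 96 fell, and with scaling to equal totals 188 rose and 141 fell. Of the non-targeting guides 12 of 131 passed. Without either sorafenib library 0 guides passed, and 1485 and 1499 did without DMSO replicate 1 and 2.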

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

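Library weights and the rank test under other settings were chosen after the data were seen. So was the Mediator list under other settings, except for scaling on the non-targeting guides, an estimated correlation and fry, which were planned. Among counts of calls, 64 stayed within 1.5 times of the main count and 44 did not. For lists, 1387 comparisons stayed on the same side of the threshold, nearly all of them uncalled throughout, 15 lost a call and 2 gained one. For single genes, none of which was called at first, 390 stayed uncalled with the same direction, 117 gained a call and 4 turned direction. Scalings, pseudocount and filters left the gene counts at 0 in all 3 comparisons.

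For genes in sorafenib vs DMSO, limma called 0, against 82 with the median over guides, 36 with a variance trend and 7 with robust rank aggregation, and 0 to 360 without 1 replicate. For genes in DMSO vs untreated it called 0, and 0 to 276 without 1 replicate. For genes in sorafenib vs untreated it called 0, against 40, 13 and 2 in the same order, 25 with library weights, 107 with only the groups compared and 0 to 107 without 1 replicate. For guides in sorafenib vs DMSO the main count of 812 became 2319 with DESeq2 and 0 to 2192 without 1 replicate. For guides in DMSO vs untreated the main count of 3 became 43 with scaling on the non-targeting guides, 0 with equal totals, 46 with a pseudocount of 10, 21 with no filter, 177 with a mean of at least 100, 0 with only the groups compared, 61 with edgeR, 1280 with DESeq2 and 0 to 1245 without 1 replicate. For guides in sorafenib vs untreated the main count of 411 became 680 with a mean of at least 100, 1481 with only the groups compared, 620 with edgeR, 1884 with DESeq2 and 0 to 1499 without 1 replicate. Where a lone library of a group remains, it is assumed to vary like the others. With a DMSO library left out, the spread comes from the sorafenib pair alone, and with a sorafenib library left out from the wider DMSO pair alone. For the other changes of a count the cause was not tested.

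The rank test's 7 genes in sorafenib vs DMSO became 1 to 6 without 1 replicate. Its 2 genes in sorafenib vs untreated became 5 with scaling on the non-targeting guides, 6 with a pseudocount of 10, 5 with a mean of at least 100 and 3 to 4 without 1 replicate, and both genes were among these each time. ATF7IP passed in all 10 other settings in sorafenib vs DMSO, SPEN and BRD1 in 9, IREB2 and USP22 in 7, MED15 in 6 and CHD7 in 5. CARM1 passed in 1.

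CARM1 kept its direction in sorafenib vs DMSO throughout, from -1.38 to -1.04 without 1 replicate, and passed limma's test with a variance trend (-1.21) and without either DMSO library. With the median over guides it was at -0.78 (adjusted p = 0.0542), and without sorafenib replicate 1 or 2 its adjusted p was 0.79 or 0.746. With an estimated correlation, on 2 residual degrees of freedom, the Mediator call ended, and fry, which asks about no change at all, did not pass. The median was 0.57 in both, as in the main setting. Without 1 replicate it was 0.49 to 0.69, and the call ended without DMSO replicate 2 (0.56). Directions turned with the median over guides for TARDBP in sorafenib vs DMSO (0.46), LSM10 (0.0598) and PRMT3 (0.0146) in DMSO vs untreated, and RBM3 in sorafenib vs untreated (-0.0381); the cause was not tested.

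Same-numbered DMSO and sorafenib libraries showed no shared deviation (correlation of same-numbered deviations 0.05 over genes and -0.002 over guides, 2 pairs). With 2 pairs this cannot tell whether the libraries were handled in pairs. With the replicate block, limma called 0 genes and 646 guides in sorafenib vs DMSO, the rank test 7 genes, and CARM1 was at -1.21 (adjusted p = 0.309).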

Other observations

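The 3 tests on guide changes were chosen after related results had been seen; the tests on Mediator genes and on DMSO library 1 were fixed before their own values were computed, though after the patterns they address had been seen. In sorafenib against DMSO, several gene families held members on both sides of 0, none of them past limma's test. Among oxygenases that use 2-oxoglutarate, ALKBH7, a mitochondrial protein, was at -1.19 ± 0.19, with 6 of 6 guides lower, and EGLN3, a prolyl hydroxylase of hypoxia-inducible factors, at 0.71 ± 0.19, with 6 of 6 guides higher. Among sirtuins, SIRT6 was at -0.92 ± 0.16 (4 of 6 guides lower) and SIRT1 at 0.55 ± 0.15 (5 of 6 guides higher). In the Polycomb complex PRC2, 5 of 8 genes were below 0, with a median of -0.18, among them the accessory subunit JARID2 (-0.41 ± 0.10, 4 of 6 guides lower). Its core subunits EZH2 (1.43 ± 0.47, 6 of 6 guides higher) and SUZ12 (0.97 ± 0.15, 3 of 6 guides higher) were above 0. Both were below 0 in DMSO against untreated (-1.18 and -1.35), which shares the DMSO libraries. In sorafenib against DMSO the SWI/SNF subunit BRD7 was at 2.32 ± 0.62, with 6 of 6 guides higher, 1 of them past limma's guide test. Among RNA-binding proteins, HNRNPR was at -1.05 ± 0.12, with 4 of 6 guides lower. The reader IGF2BP2 of methylated RNA was at -0.68 ± 0.14, with 6 of 6 guides lower.

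Between sorafenib and DMSO, like shares of targeting and non-targeting guides passed the guide test, while the sizes of their changes differed (SD of the log2 ratio 1.30 and 0.70). A test whether the share is lower for non-targeting guides (one-sided Fisher's exact test, p = 0.719) does not decide on drift of single guides, since the shares had been seen. Counting error of the reads as the whole cause is argued against: the SD of the non-targeting log2 ratio was 13.1 times what it gives, and the spread within groups alone gives 8.08 times. Drift of the same size for all guides, as the whole cause of the changes of gene means, is argued against too. The SD of gene means was 0.57, against a median of 0.53 when guides were dealt to genes at random. The share of 10000 deals as large was 0.0007. The deals did not match guides on abundance, so they cannot decide on drift that is larger for rare guides. What besides counting error causes the calls of single guides stays open. How large any part common to guides of a gene is stays open too, since the deals keep any effect of the targets. Sets of non-targeting guides had an SD of 0.25, and effects of cutting in amplified regions were not tested.

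Mediator genes had a higher median in sorafenib against DMSO, 0.57, a call of camera's preset correlation that was lost with an estimated correlation (adjusted p = 0.961) and without DMSO replicate 2 (adjusted p = 0.0634). Extra guide loss in DMSO 1 is argued against as the whole cause, since without that library the median was 0.49 and the share of 10000 random lists as high was 0.0001, the smallest they can give. So are guides that were rare over all libraries. With the median over guides of a mean of at least 100, the median was 0.44 and the share again 0.0001. That mean is over all libraries, so guides near the floor in DMSO alone could stay, and an effect of these is not decided. Lists matched on the change from untreated to DMSO reached the Mediator median in a share of 0.0004. This does not decide on weaker depletion of whatever had dropped in DMSO. The change rests on 1 untreated library whose time of collection is not given, so it may not measure depletion. A lower need for Mediator under sorafenib may account for the higher median, as a hypothesis from the same data. Whether it would be particular to Mediator was not tested. Of 39 genes listed as cell-essential, 29 were above 0 and 10 below, with a median of 0.30 (camera, adjusted p = 0.424). Medians of the 25 lists fixed beforehand that did not pass, this one included, ran from -0.23 to 0.61. New cultures with single Mediator knockouts would test the hypothesis. Whether Mediator genes vary together between libraries stays open, since their estimated correlation, 0.08, rests on 2 residual degrees of freedom. The shares of random lists treat genes as independent.

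In DMSO 1, 152 targeting guides were at 0 that were read in DMSO 2. Lower depth is argued against: DMSO 2 thinned to the reads of DMSO 1 had at most 94 guides at 0 in 100 draws, against 232 in DMSO 1. These guides were rare already in the untreated library (median 186.5 reads, against 3012 for all targeting guides). They hit 12 genes at least 2 times, and the share of abundance-matched draws with as many was 0.792, which is consistent with a loss that depends on abundance alone, as in a bottleneck of cells. No biological explanation was tested, and KDM4C was the gene with the most such guides (3).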
